A study of Mus musculus with 5 samples.

How the data were processed

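The series holds 5 droplet libraries of single-cell RNA (10x Genomics 3' chemistry), 1 of LMPP, 1 of CMP and 3 of GMP, each sorted from c-Kit-enriched bone marrow of Balb/C mice. Per the submitters' processing notes, reads were aligned to the mm10 mouse genome with Cell Ranger 3.1.0 and analysed with Seurat 3.1.1, whereas per the file headers the matrices were written by Cell Ranger 6.1.1. The deposited matrices hold counts of UMIs per gene and barcode, and all 55450 gene identifiers match GENCODE release M21. How barcodes were kept was not stated.

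The deposited barcodes numbered 8116 for LMPP, 7389 for CMP, and 9510, 9993 and 8021 for GMP replicates 1, 2 and 3. Barcodes with fewer than 500 genes, fewer than 1000 UMIs or more than 10% mitochondrial UMIs were removed (83, 77, 387, 194 and 184). Doublets were called from simulated doublets at a rate of 0.8% per 1000 barcodes and removed (522, 432, 694, 783 and 503). The libraries were not thinned for the main results, and the smallest summed to 80219621 UMIs after filtering. Counting error is small beside the spread between GMP libraries, except for genes with few UMIs, for some of which counting intervals, limits or UMI counts are given.

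Cells were scaled to 10000 UMIs and clustered on 2000 variable genes, 30 principal components and 20 neighbours with the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). A cluster took the name of a class when at least 3 of its markers were raised 1.5-fold over the other cells at 20 CPM or more, with 5 CPM added to each side. In addition, a marker had to be among the 10 leading genes of the cluster, or at least 2 of every 3 markers detected had to be raised. Clusters whose median UMIs lay under 1 in 3 of that of the libraries were left unnamed unless a marker led them. The additional conditions on names were set after the clusters were seen. Shares of single libraries have exact 95% Clopper-Pearson intervals.

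UMIs were summed per library and tested with the edgeR quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on TMM factors, with filterByExpr, a prior count of 2 and Benjamini-Hochberg adjustment at 0.05. The fit has 2 residual degrees of freedom, all from GMP, so the lone CMP and LMPP libraries are assumed to vary like the GMP libraries. The series does not say whether the GMP libraries came from separate animals. CMP and LMPP were compared without a test, by exact Poisson intervals, at 4-fold or more. Gene lists were fixed in advance and tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data. The second form refers its statistic to the 2 residual degrees of freedom of the fit, so few lists can pass it after adjustment. Medians of lists in CMP against LMPP were placed among 10000 random lists drawn from 20 bins of expression.

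Within GMP, each cell's UMIs were divided at random between 2 parts, classes were named on one part and genes were tested on the other with library as a block. GMP and CMP were also compared within the named class with the most CMP cells among those with at least 100 cells in each of these 4 libraries. The basophil and mast cell-like class, with 176 CMP cells, also met the minimum and was not tested. Pairs of regulators were tested after thinning each cell to 2000 UMIs, as the log2 odds ratio of detection over all cells of a library. S and G2M phase genes were summed as a percent of UMIs.

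Genes were named by a rule. For each comparison these were the 10 with the largest change in each direction among those past the threshold, with all GMP libraries on one side and at least 50 CPM in the higher group. Predicted and mitochondrial genes were counted but not named. All gate genes were named, and of each list up to 4 members: the 2 with the largest change past the threshold and the 2 with the highest mean CPM. Within GMP classes and within the shared class, markers of the classes compared were left out. For CMP against LMPP, the 10 highest and 10 lowest folds under the size rule were named. A few genes that the rule names are not reported here. Groups, comparisons, tests, lists, the rule and most alternatives were set before the data were examined.

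The alternatives tried were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, all deposited barcodes, doublet calls kept, libraries thinned to 80219621 UMIs or to 6880 cells, only the groups compared, and each GMP replicate left out. Others were Leiden resolutions of 0.5 and 2, clustering without cell cycle genes, no library block, undivided counts, thinning to 1000 and 4000 UMIs, and means over cells. Scaling by total UMIs and leaving out the neutrophil-like cluster were chosen after seeing the data. The tests were also run on simulated data with 200 changed genes each. They recovered 90% of 2-fold changes for GMP against CMP, 94% for GMP against LMPP, 80% within the shared class and 100% within GMP. False calls numbered 9, 17, 8 and 11 in that order. The changed genes were drawn from the better expressed ones, and the lone CMP and LMPP libraries were given the fitted dispersion. These shares therefore do not cover weakly expressed genes, or CMP and LMPP samples that vary more than GMP. The trajectory of cells between the populations was not analysed, and free RNA was not subtracted because empty droplets were not used here. Figures were drawn with matplotlib 3.10.9.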

Results

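Single-cell RNA was profiled from mouse bone marrow progenitors (Balb/C animals) in 5 droplet libraries of sorted lineage-negative, c-Kit-positive cells. LMPP, the lymphoid-primed multipotent progenitor, was sorted as positive for Sca-1, CD34 and Flt3 and has 1 library. CMP, the common myeloid progenitor, was sorted as negative for Sca-1, positive for CD34 and low for CD16/32, and has 1 library. GMP, the granulocyte-monocyte progenitor, was sorted as negative for Sca-1, positive for CD34 and high for CD16/32, and has 3 libraries. The deposited counts came to 93770259 UMIs (unique molecules) for LMPP, 90067195 for CMP, and 112327644, 137141095 and 127387528 for GMP replicates 1, 2 and 3. After filtering, 7511 LMPP cells, 6880 CMP cells, and 8429, 9016 and 7334 GMP cells remained, with medians of 9226, 10052.5, 10685, 12773.5 and 15082.5 UMIs per cell in that order. The series calls the GMP libraries biological replicates without saying whether they came from separate animals, so their spread is one between samples. P-values against CMP and LMPP rest on that spread alone and hold none between CMP or LMPP samples. P-values between classes within GMP rest on how the class difference varies over the 3 GMP libraries.

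The GMP libraries resembled each other closely, and replicate 1 lay farthest from the rest. Across genes, which are not independent replicates, Pearson's r of log2 CPM (UMI counts scaled to the library total) was 0.990 between replicates 1 and 2, 0.990 between 1 and 3, and 0.995 between 2 and 3. Over 2675 genes the SD of the deviation from the GMP mean was 0.16 on the log2 scale in replicate 1, 0.09 in replicate 2 and 0.11 in replicate 3. The edgeR common dispersion gave a biological coefficient of variation of 13.3%. Genes of the immediate early and heat shock list, which respond within minutes to handling or signals, summed to 3656 CPM in GMP replicate 1, 2424 in replicate 2 and 2659.5 in replicate 3.

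Clustering, with names taken from fixed marker lists, asked which cell classes each sorted population held. In GMP, 37.6% ± 2.66 (SD, n = 3) of cells were monocyte-like, with Irf8, F13a1, Ly86 and Csf1r raised, and 33.5% ± 1.26 were granulo-monocytic-like, with Prtn3, Ctsg, Prss57 and Ms4a3 raised. Basophil and mast cell-like cells, led by Prss34, Ms4a2 or Gzmb, made up 6.58% ± 1.41 of GMP, and eosinophil-like cells, led by Prg2 and Epx, 1.62% ± 0.216. In CMP, 28.0% of cells (95% exact Clopper-Pearson interval 27.0 to 29.1) were erythroid-like, with Gata1, Klf1 and Car1 raised; the platelet factor gene Pf4 was also among their leading genes. At resolution 2, 582 CMP cells (8.46%) formed a megakaryocyte-like cluster led by Pf4, and 19.2% of CMP were erythroid-like. A further 6.26% of CMP cells (5.70 to 6.86) were B cell-like, led by Ebf1, Dntt and Il7r, although no cluster earned that name at the lower Leiden resolution of 0.5. Monocyte-like cells made up 2.60% of CMP (2.24 to 3.01) and basophil and mast cell-like cells 2.56% (2.20 to 2.96). No eosinophil-like cell was found among 6880 CMP cells, which allows a share of up to 0.0436%. In LMPP, 87.9% of cells (87.2 to 88.7) were stem and multipotent-like, with Hlf, Mecom and Meis1 raised. B cell-like cells made up 3.42% of LMPP (3.02 to 3.86, and 0 at resolution 0.5), and 69 cells (0.919%, 0.715 to 1.16) were neutrophil-like, led by Ngp and Camp. At resolution 2 that name took in 133 LMPP cells and 8.75% ± 3.12 of GMP, where 0.0215% ± 0.0205 had it in the main clustering.

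An unnamed cluster held 47.8% of CMP cells and was led by Nr4a1, Socs3 and Cdkn1a, with Dntt, Flt3, Satb1 and Notch1 also raised. At resolution 0.5 a cluster led by Dntt, Nr4a1 and Socs3, with 3672 CMP cells, was named lymphoid-primed-like, a name that 1809 LMPP cells (24.1%) also had there, and at resolution 2 one led by Nr4a1 and Socs3, with 1068 CMP cells, was named stem and multipotent-like. Of the 3484 cells of the unnamed cluster, 3290 came from CMP, and 2653 of the 2676 cells of the largest stem and multipotent-like cluster came from LMPP. Neither CMP nor LMPP has another library to show whether such a cluster belongs to the cell type or to the library. The monocyte-like and granulo-monocytic-like shares were higher in each of the 3 GMP libraries than in CMP and LMPP, but an exact test of 3 libraries against 1 cannot give a p below 0.25.

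**Figure D1:**
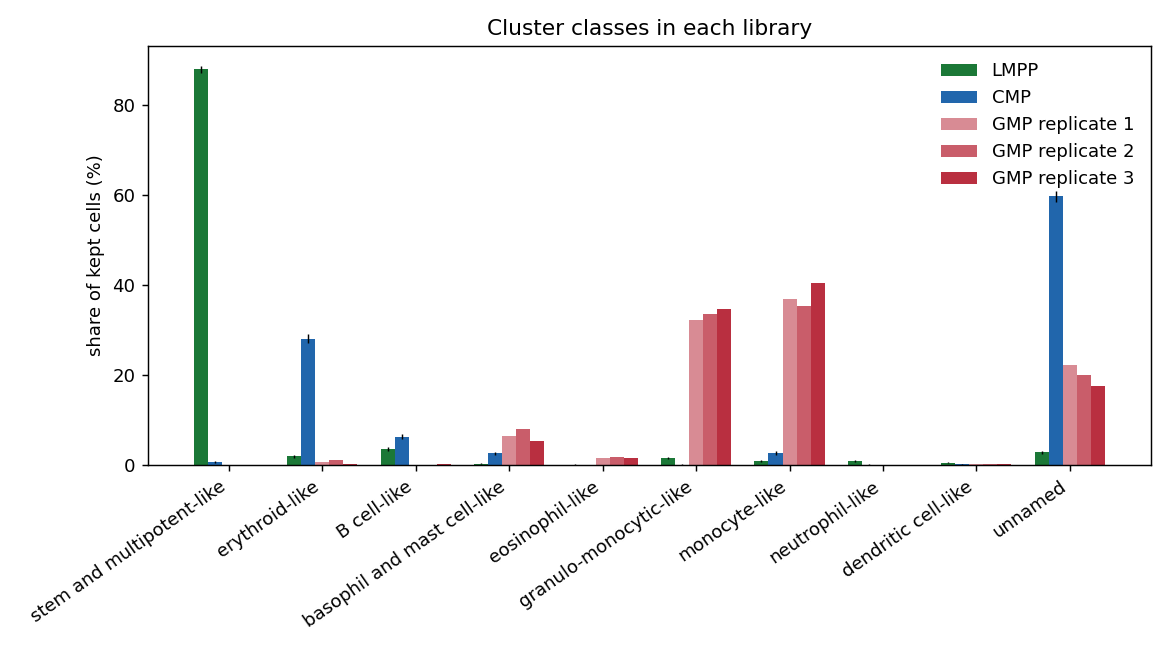
Share of kept cells (%) in each named cluster class, with 1 bar per library and exact 95% intervals on the single LMPP and CMP libraries. Stem and multipotent-like cells make up 87.9% of LMPP, erythroid-like cells 28.0% of CMP, and monocyte-like cells 37.6% of GMP on average.

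Genes of the sorted antigens were compared to check the labels. Fcgr3 and Fcgr2b, which encode the CD16/32 receptors and whose similar sequences may share reads, were higher in GMP than in CMP by 2.31 ± 0.19 and 2.48 ± 0.21 (log2, ± SE), with adjusted p = 0.00013 and 0.000125. Against LMPP the differences were 4.41 ± 0.23 and 2.61 ± 0.21, with adjusted p = 7.66e-06 and 5.14e-05. Flt3, the receptor that LMPP was sorted on, reached 94.2 CPM in LMPP, 44.0 in CMP and 5.02 ± 0.572 (SD, n = 3) in GMP. Ly6a, which encodes Sca-1, stood at 12.9 CPM in LMPP, 0.895 in CMP and 0.991 ± 0.159 in GMP. Cd34 was lower in GMP than in CMP (-1.16 ± 0.14, adjusted p = 0.000605) and LMPP (-1.14 ± 0.14, adjusted p = 0.000313). Kit was lower in GMP than in LMPP (-1.09 ± 0.14, adjusted p = 0.000405). Its difference from CMP was -0.17 ± 0.14 (adjusted p = 0.411), and that of Ly6a was 0.15 ± 0.26 (adjusted p = 0.703), neither past the threshold of 0.05. Of the 12 comparisons of gate genes, 10 passed, each with all 3 GMP libraries on the same side.

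**Figure D2:**
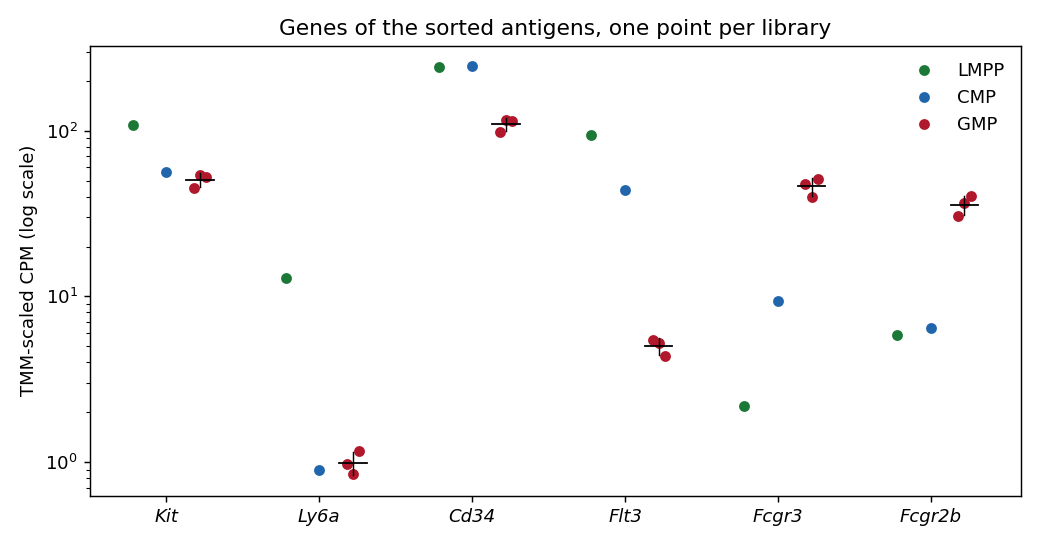
TMM-scaled CPM (log axis) of the genes of the sorted antigens, with 1 point per library, and a black line at the GMP mean with its SD over 3 libraries. Ly6a is highest in LMPP at 12.9 CPM, and Fcgr3 is highest in GMP at a mean of 46.3 CPM.

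GMP was compared with CMP for the genes that differ between these successive myeloid populations. GMP carried more RNA of the granulo-monocytic, azurophil granule and eosinophil lists, and less RNA of the lymphoid-primed, erythroid and megakaryocyte lists, by the camera test at a preset correlation. With an estimated correlation none of these lists passed (adjusted p = 0.319 to 0.362), and without GMP replicate 1 the eosinophil list did not pass (0.0521). Elane, which encodes neutrophil elastase, averaged 13381 ± 1662 CPM (SD, n = 3) in GMP against 208 in CMP, a log2 difference of 6.01 ± 0.28 (SE). Cebpe, a transcription factor of granulocyte maturation, averaged 168 ± 12.6 against 5.64 CPM (4.90 ± 0.19). Dntt, the template-independent DNA polymerase of lymphoid progenitors, averaged 0.634 ± 0.219 CPM in GMP against 255 in CMP (-8.63 ± 0.24). By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 6431 of 19729 genes passed 0.05, with 2668 higher and 3763 lower in GMP. Of these, 1218 were over 2-fold higher and 2673 over 2-fold lower.

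Among the genes most raised in GMP over CMP, Prg2, the eosinophil major basic protein, differed by 10.88 ± 0.36 (log2 ± SE, adjusted p = 4.56e-06; 6 CMP UMIs, 95% counting interval of the ratio 874 to 5187) and Prss34, a basophil protease, by 8.98 ± 0.30 (adjusted p = 4.56e-06). Epx, eosinophil peroxidase, had no UMI in CMP and was at least 348-fold higher in GMP, against a floor of 3 counts in the CMP library. The lectin receptor gene Clec4a2 differed by 7.73 ± 0.32, the myeloid receptor gene Trem3 by 4.89 ± 0.33, the membrane protein gene Ms4a3 by 5.78 ± 0.23 and the guanine deaminase gene Gda by 4.71 ± 0.26. The surface antigen genes Ly6c1 and Ly6c2, close paralogs that may share reads, differed by 5.03 ± 0.26 and 4.87 ± 0.20. Among the genes most reduced in GMP were the carbonic anhydrases Car1 (-5.91 ± 0.47, adjusted p = 0.000107) and Car2 (-4.32 ± 0.29, adjusted p = 5.23e-05) and the platelet factor gene Pf4 (-4.21 ± 0.62, adjusted p = 0.00184). Zfpm1, a partner of GATA factors, differed by -3.56 ± 0.25, and Gimap1, a lymphocyte GTPase gene, by -3.71 ± 0.30. Nr4a1, an activity-induced nuclear receptor, differed by -4.72 ± 0.24, Ctla2a by -4.18 ± 0.32 and Gcnt2 by -3.82 ± 0.21. All 3 GMP libraries lay on the same side of CMP for each of these genes.

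Of the fixed lists of myeloid genes, all 6 granulo-monocytic genes passed as higher, with Prtn3 at 3.47 ± 0.22, Mpo (myeloperoxidase) at 2.25 ± 0.22 and Prss57 at 3.82 ± 0.17. The camera test gave an adjusted p = 7.85e-08 for this list, and an adjusted p = 0.319 with an estimated correlation. Of 7 azurophil granule genes, 6 were higher and 1 did not pass (camera adjusted p = 5.49e-08, adjusted p = 0.319 with an estimated correlation). Of 10 neutrophil genes, 7 were higher and 3 lower, with Fcnb at 6.90 ± 0.36 (15 CMP UMIs, 95% counting interval of the ratio 73.7 to 218) and Serpinb1a at 1.25 ± 0.15 (camera adjusted p = 0.00159, adjusted p = 0.319 with an estimated correlation). Of 9 basophil and mast cell genes, 5 were higher, 1 lower and 3 not past, with Mcpt8 at 2.90 ± 0.17 (camera adjusted p = 0.00159, adjusted p = 0.319 with an estimated correlation). Eosinophil genes were higher in 4 of 5 cases (camera adjusted p = 0.00149, adjusted p = 0.362 with an estimated correlation), monocyte genes in 6 of 10 with 1 lower (camera adjusted p = 0.0106, adjusted p = 0.399 with an estimated correlation), and specific and gelatinase granule genes in 7 of 11 with 3 lower (camera adjusted p = 0.0193, adjusted p = 0.362 with an estimated correlation). S100a8 and S100a9, calcium-binding proteins of neutrophils, differed by 4.06 ± 0.19 and 3.89 ± 0.29. Without the neutrophil-like cluster, which held 2 CMP cells, these values were 6.90 and 6.46. Then 7 of 10 neutrophil genes and 7 of 10 specific and gelatinase granule genes were higher and none lower, so the lower calls rest on those cells. The differences of Camp (-0.95), Ltf (-2.13) and Ngp (-0.18) still pointed down without passing 0.05. Without GMP replicate 1 the camera adjusted p was 0.0521 for the eosinophil list and 0.0640 for each of the monocyte and specific granule lists.

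Stem cell, lymphoid-primed, erythroid, megakaryocyte, transcription factor, interferon and immediate early lists were lower in GMP than in CMP. All 7 stem and multipotent genes were lower (camera adjusted p = 1.12e-06, adjusted p = 0.319 with an estimated correlation), with Hlf at -3.47 ± 0.19, Mecom at -3.34 ± 0.15 and Meis1 at -2.65 ± 0.16. All 7 lymphoid-primed genes were lower (camera adjusted p = 3.38e-07, adjusted p = 0.319 with an estimated correlation), with Satb1 at -1.50 ± 0.12. All 8 erythroid genes were lower (camera adjusted p = 3.38e-07, adjusted p = 0.319 with an estimated correlation), with Ermap at -6.90 ± 0.23 and Blvrb at -1.49 ± 0.19. All 7 megakaryocyte genes were lower (camera adjusted p = 4.58e-06, adjusted p = 0.362 with an estimated correlation), with Plek at -2.33 ± 0.18. Of 39 lineage transcription factors, 8 were higher, 22 lower and 9 not past, with Gata3 at -5.08 ± 0.29 and Irf8, a monocyte and dendritic cell regulator, at 0.82 ± 0.17 (camera adjusted p = 0.000177, adjusted p = 0.319 with an estimated correlation). Of 13 interferon response genes, 10 were lower, 2 did not pass and 1 was higher, with Rtp4 at -3.14 ± 0.22 and Bst2 at 2.02 ± 0.37 (camera adjusted p = 0.000144, adjusted p = 0.319 with an estimated correlation). Of 15 immediate early and heat shock genes, 11 were lower and 4 did not pass, with Btg2 at -2.31 ± 0.15, Egr1 at -2.02 ± 0.20 and Jun at -1.21 ± 0.22 (camera adjusted p = 5.01e-05, adjusted p = 0.319 with an estimated correlation). Of the lists of further lineages, B cell genes were lower in 4 of 8 cases and higher in 1 (camera adjusted p = 0.0112, adjusted p = 0.319 with an estimated correlation). The dendritic cell list (2 higher, 4 lower, camera adjusted p = 0.339), the T and NK cell list (1 higher, 4 lower, 0.0919, but 0.0369 without GMP replicate 2 and 0.0413 without replicate 3) and the macrophage list (3 higher, 0 lower, 0.395) did not pass. Adjusted over the list alone, 23 transcription factors and 5 B cell genes were lower, 1 immediate early gene was higher and 12 were lower, and the other counts given for these lists were the same. With scaling by total UMIs, 4 transcription factors were higher and 26 lower, and 6 monocyte genes higher and 3 lower.

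Metabolic and protein folding lists were higher in GMP than in CMP. Of 79 oxidative phosphorylation genes, 57 were higher and 1 lower, or 60 and 1 adjusted over the list alone, with Cox4i1 at 0.94 ± 0.16 and Uqcrq at 1.35 ± 0.16 (camera adjusted p = 7.86e-18, adjusted p = 0.319 with an estimated correlation). Cox6a2, which encodes an isoform best known from heart and skeletal muscle, was the lower one (-2.74 ± 0.19). Of 14 endoplasmic reticulum folding genes, 12 were higher, or 13 adjusted over the list alone, with the chaperone genes Calr at 1.84 ± 0.20, Sdf2l1 at 1.94 ± 0.24 and Hsp90b1 at 1.53 ± 0.15 (camera adjusted p = 2.18e-09, adjusted p = 0.319 with an estimated correlation). Of 12 glycolysis genes, 9 were higher and 2 lower, with Pgam1 at 1.34 ± 0.14 and Hk2 at 1.22 ± 0.20 (camera adjusted p = 0.00068, adjusted p = 0.362 with an estimated correlation). Ribosomal protein genes passed as higher in 9 of 82 cases and lower in 1, or 3 and 0 adjusted over the list alone, with a camera adjusted p = 9.71e-05 and an adjusted p = 0.362 with an estimated correlation; their median of 0.22 turned to -0.09 when libraries were scaled by total UMIs, with 2 higher and 9 lower. That scaling, chosen after seeing the data, moved the median over all genes from -0.04 to -0.34 and the split to 1435 higher and 5941 lower, so changes are given relative to the TMM-scaled library. It left 30 oxidative phosphorylation, 11 folding and 4 glycolysis genes higher. Leaving out GMP replicate 1 raised the number of genes higher in GMP from 2668 to 4504. Of 34 mitochondrially encoded genes, 4 were higher than in CMP, or 2 adjusted over the list alone (camera adjusted p = 0.00510, adjusted p = 0.628 with an estimated correlation). They summed to 9287 CPM in GMP replicate 1, below CMP (10198) and LMPP (10482), but to 14610 and 15509 in replicates 2 and 3.

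GMP was compared with LMPP for the genes that separate the granulocyte-monocyte progenitor from the lymphoid-primed one. GMP carried more RNA of Mpo, at 8291 ± 1039.5 CPM (SD, n = 3) against 393 in LMPP (4.40 ± 0.26, log2 ± SE) and Ctsg, cathepsin G, at 4033 ± 322 against 199 (4.34 ± 0.22). LMPP carried more RNA of the stem cell regulator Hlf, at 361 CPM against 5.32 ± 1.13 in GMP (-6.08 ± 0.20) and Mecom at 79.2 against 2.31 ± 0.297 (-5.10 ± 0.15). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment passed 11298 of 19729 genes, with 5083 higher and 6215 lower in GMP. Of these, 2737 were over 2-fold higher and 4708 over 2-fold lower. The DESeq2 Wald test gave 4714 higher and 4250 lower. The same 3 GMP libraries entered the comparison with CMP, so the pair of comparisons is not independent.

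Among genes with at least 50 CPM in the higher group, Prg2 led those raised over LMPP (6.81 ± 0.26, adjusted p = 3.59e-06), followed by Ly6c2 (5.03 ± 0.21, adjusted p = 4.67e-06) and Ly6c1 (4.59 ± 0.25, adjusted p = 1.04e-05). Elane was higher by 4.56 ± 0.26, Ms4a3 by 4.42 ± 0.21, Cebpe by 4.27 ± 0.18, the haptoglobin gene Hp by 4.32 ± 0.20 and the annexin gene Anxa3 by 4.16 ± 0.22. Among the genes reduced against LMPP were Dntt (-7.71 ± 0.23, adjusted p = 1.54e-06), the lymphocyte GTPase gene Gimap6 (-7.10 ± 0.33), Wfdc17 (-5.85 ± 0.16), Gcnt2 (-5.46 ± 0.22) and Car2 (-5.16 ± 0.29). Camp and Ngp, granule proteins of maturing neutrophils, were lower by -8.96 ± 0.30 and -8.27 ± 0.20, and S100a8 and S100a9 by -1.98 ± 0.13 and -2.04 ± 0.20. The 69 neutrophil-like cells held 86.2% of the LMPP UMIs of these 4 genes and Ltf together, and without that cluster S100a8 was higher in GMP by 0.94, S100a9 did not pass (0.48, adjusted p = 0.0903), and Camp and Ngp stayed lower, by -5.70 and -4.72. Igkc, the immunoglobulin kappa constant region, had 13626 UMIs in LMPP and 2 in GMP, a ratio of 17573 with a 95% counting interval of 4864 to 145123. In LMPP, 1 cell held 12386 of those UMIs and the other cells 1240, still above GMP.

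**Figure D3:**
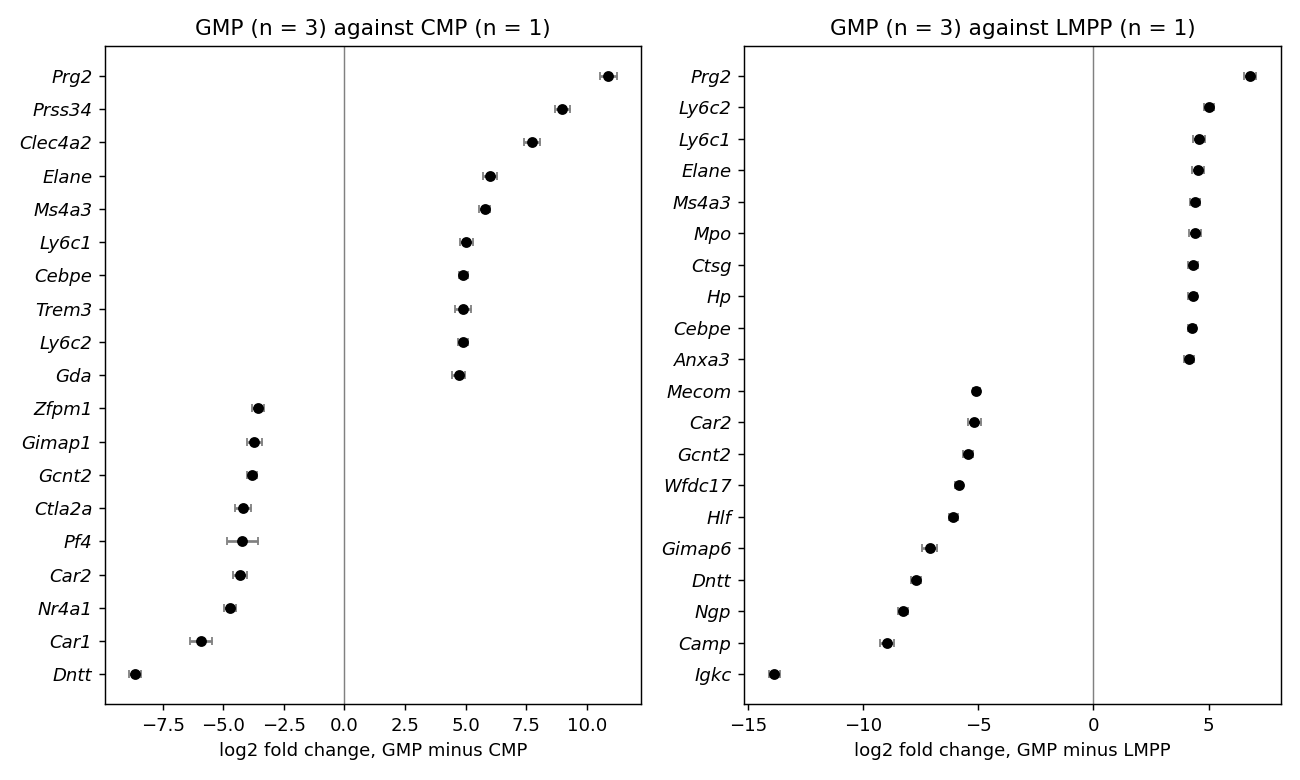
Log2 fold change of the genes named by the fixed rule, GMP minus CMP and GMP minus LMPP, with points for the edgeR estimate and bars for its standard error. Prg2 lies highest at 10.88 over CMP and 6.81 over LMPP, and the lowest genes are Dntt at -8.63 against CMP and, against LMPP, Igkc, of which 1 LMPP cell held 12386 of 13626 UMIs.

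Granulo-monocytic, azurophil granule, basophil and mast cell, monocyte and eosinophil lists were higher in GMP than in LMPP. All 6 granulo-monocytic genes passed, with Prtn3 at 3.93 ± 0.23 (camera adjusted p = 5.32e-06, adjusted p = 0.338 with an estimated correlation). Azurophil granule genes were higher in 6 of 7 cases (camera adjusted p = 9.33e-06, adjusted p = 0.338 with an estimated correlation). Of 9 basophil and mast cell genes, 8 were higher and 1 lower, with the histidine decarboxylase gene Hdc at 4.13 ± 0.23, Cpa3 at 3.71 ± 0.23 and Mcpt8 at 3.49 ± 0.18 (camera adjusted p = 0.000103, adjusted p = 0.338 with an estimated correlation). Of 10 monocyte genes, 7 were higher and 3 lower, with F13a1 at 3.97 ± 0.18, Ly86 at 3.82 ± 0.22 and Irf8 at 3.33 ± 0.20 (camera adjusted p = 0.0202, or 0.0591 without GMP replicate 1, and adjusted p = 0.471 with an estimated correlation). Eosinophil genes were higher in 4 of 5 cases, with Prg3 at 5.08 ± 0.33 (camera adjusted p = 0.00181, adjusted p = 0.376 with an estimated correlation). Of 10 neutrophil genes, 5 were higher, 4 lower and 1 not past, with a median of 0.62 and a mean of -1.45 (camera adjusted p = 0.459, adjusted p = 0.662 with an estimated correlation). Specific and gelatinase granule genes went the other way, with 9 of 11 lower and 2 higher (camera adjusted p = 0.00185, adjusted p = 0.338 with an estimated correlation). Without the neutrophil-like cluster the specific granule list had 4 higher and 4 lower (camera adjusted p = 0.727, pointing up), and the neutrophil list 6 higher and 3 lower (camera test not past 0.05).

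Lists of stem cell, lymphoid, erythroid, megakaryocyte, interferon and immediate early genes were lower in GMP than in LMPP. All 7 stem and multipotent genes were lower, with Meis1 at -3.76 ± 0.15 and Fgd5 at -5.30 ± 0.28 (camera adjusted p = 9.33e-06, adjusted p = 0.338 with an estimated correlation). All 7 lymphoid-primed genes were lower, with Satb1 at -1.55 ± 0.12 (camera adjusted p = 3.64e-05, adjusted p = 0.338 with an estimated correlation). Erythroid genes were lower in 6 of 8 cases, with Ermap at -5.79 ± 0.23 (camera adjusted p = 0.00536, adjusted p = 0.431 with an estimated correlation). Megakaryocyte genes were lower in 4 of 7 cases, with Gp9 at -2.78 ± 0.21 (camera adjusted p = 0.0402, or 0.0890 without GMP replicate 1, and adjusted p = 0.558 with an estimated correlation). Of 13 interferon response genes, 12 were lower, with Rtp4 at -3.95 ± 0.22 and Ifitm3 at -0.94 ± 0.16 (camera adjusted p = 5.10e-05, adjusted p = 0.338 with an estimated correlation). Of 15 immediate early and heat shock genes, 9 were lower and 3 higher (4 adjusted over the list alone, and 10 lower and 0 higher with scaling by total UMIs), with Fosb at -3.98 ± 0.12 and Egr1 at -3.36 ± 0.20 (camera adjusted p = 0.0167, adjusted p = 0.413 with an estimated correlation). Dendritic cell genes were lower in 6 of 8 cases and higher in 1 (camera adjusted p = 0.0182, or 0.0501 without GMP replicate 1, and adjusted p = 0.376 with an estimated correlation), and so were B cell genes (0.0258 and 0.338). The T and NK cell list (1 higher, 3 lower, camera adjusted p = 0.374) and the macrophage list (2 higher, or 3 adjusted over the list alone, and 4 lower, 0.540) did not pass. The sum of the immediate early and heat shock list was 8536 CPM in LMPP and 7393 in CMP, against 3656 in GMP replicate 1, the highest of the GMP libraries.

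Metabolic and folding lists were higher in GMP than in LMPP. Of 79 oxidative phosphorylation genes, 73 were higher and 1 lower, or 75 and 1 adjusted over the list alone, with Ndufs6 at 1.92 ± 0.15 and Uqcrq at 2.13 ± 0.17 (camera adjusted p = 3.17e-21, adjusted p = 0.338 with an estimated correlation). Glycolysis genes were higher in 10 of 12 cases, with Pgam1 at 2.22 ± 0.15 and Gapdh at 1.56 ± 0.17 (camera adjusted p = 8.27e-06, adjusted p = 0.338 with an estimated correlation). Endoplasmic reticulum folding genes were higher in 13 of 14 cases, with Calr at 2.87 ± 0.21 (camera adjusted p = 1.54e-06, adjusted p = 0.338 with an estimated correlation). Ribosome biogenesis genes were higher in 14 of 15 cases, or 4 with scaling by total UMIs, with Srm at 1.97 ± 0.16 and Pa2g4 at 1.28 ± 0.16 (camera adjusted p = 8.27e-06, adjusted p = 0.338 with an estimated correlation). Ribosomal protein genes were higher in 47 of 82 cases, or 49 adjusted over the list alone (camera adjusted p = 4.46e-10, adjusted p = 0.338 with an estimated correlation), but their median of 0.60 turned to -0.02 with scaling by total UMIs, where 10 were higher and 14 lower. With that scaling the median over all genes moved from -0.10 to -0.71, and 2150 genes were higher and 10210 lower. Adjusted over the list alone, the counts of the other lists named in the comparison with LMPP were the same.

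**Figure D4:**
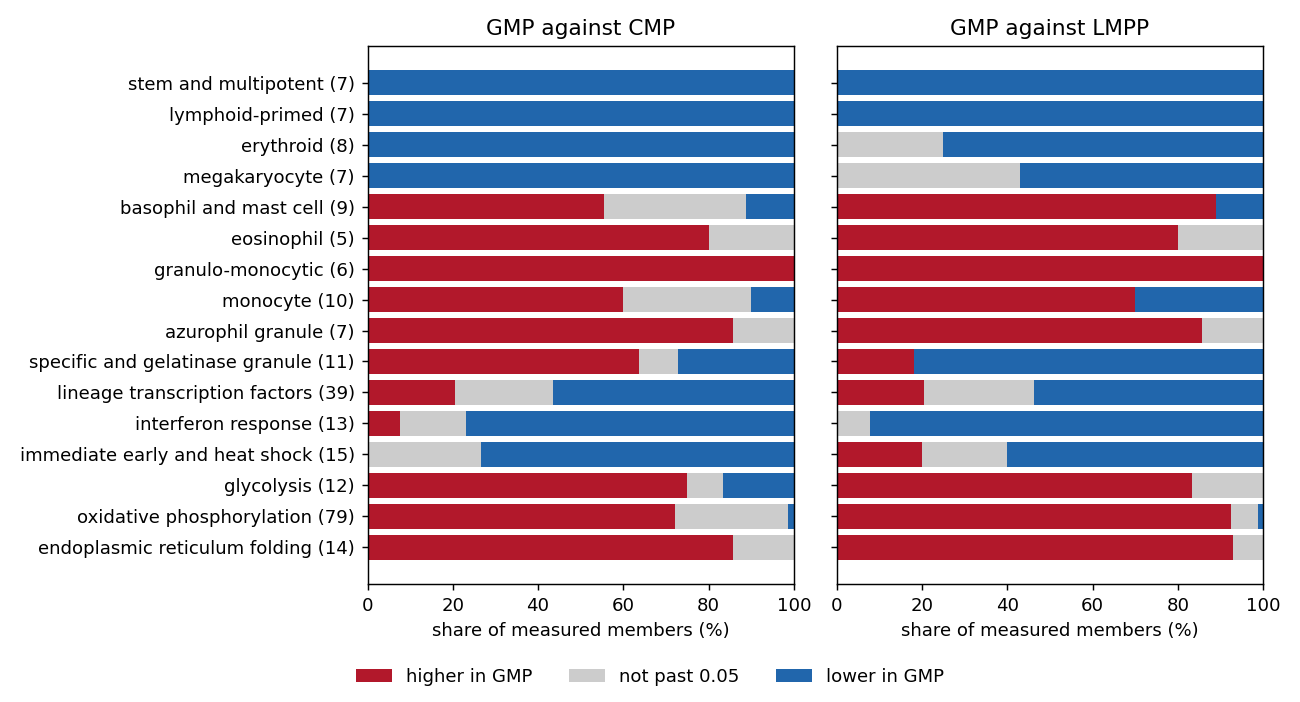
Share of the measured members of each fixed list (number in parentheses) that was higher, lower or not past 0.05 in GMP, against CMP on the left and LMPP on the right, with TMM scaling. All 7 stem and multipotent genes and all 7 lymphoid-primed genes are lower in both comparisons, and all 6 granulo-monocytic genes are higher.

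CMP and LMPP were compared as single libraries, so values are given with exact Poisson 95% intervals for counting error and without a test. CMP carried more RNA of the basophil and mast cell and the megakaryocyte lists, and LMPP more of the stem and multipotent list. Cpa3, mast cell carboxypeptidase, was 12.4-fold higher in CMP, where LMPP held 8.07 CPM (7.56 to 8.61). Apoe, apolipoprotein E, was 8.72-fold higher in CMP, Pf4 8.46-fold, and Irf8 5.70-fold. Mpo was 4.43-fold higher in CMP, at 1741 CPM (1732 to 1749.6) against 393 (389 to 396). Arl2bp was 9.96-fold higher in CMP, Phlda1 8.93-fold, the heme synthesis gene Alad 6.15-fold, the cell cycle inhibitor gene Cdkn1a 5.03-fold and Slpi 4.78-fold. Hlf was 6.09-fold higher in LMPP, at 361 CPM (357 to 364) against 59.2 (57.6 to 60.8), and the transcription factor genes Klf4, Klf2 and Fosb were 6.90-, 5.77- and 5.19-fold higher. Of the 15 immediate early and heat shock genes, which include Fosb, 10 were higher in CMP.

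Sfi1 was 4.85-fold higher in LMPP than in CMP. S100a8 was 65.9-fold, S100a9 61.2-fold, Camp 28.1-fold and Ngp 25.7-fold higher in LMPP, whose 69 neutrophil-like cells held 86.2% of the UMIs of these genes and Ltf. The neutrophil-like cluster was then left out of both libraries, which took 69 LMPP cells and 2 CMP cells. Outside it these 5 genes still summed to 297 CPM of total UMIs in LMPP against 4.76 in CMP, or 62.5-fold. All cells gave 2129 and 35.6 CPM, or 59.8-fold, so the sums fell in both libraries. Igkc was 1172-fold higher in LMPP, with 12386 of its 13626 UMIs in 1 cell. The other LMPP cells held 1240 Igkc UMIs against 9 in CMP, so LMPP stayed higher without that cell. At 4-fold or more with at least 50 CPM in the higher library, 13 genes were higher in CMP and 12 in LMPP; with CPM of total UMIs these counts were 8 and 27, and at 2-fold 149 and 46. Against 10000 random lists of similar expression, the medians of the erythroid, megakaryocyte, basophil and mast cell, monocyte and oxidative phosphorylation lists lay at percentile 100 toward CMP. The medians of the stem and multipotent, dendritic cell, macrophage, neutrophil, specific and gelatinase granule, and G2M phase lists lay at percentile 0, toward LMPP. Members of a list can vary together, which random lists need not do, and each side is a single library. These percentiles are therefore not tests. LMPP held 34 dendritic cell-like cells and CMP 8. Of the 79 oxidative phosphorylation genes, 75 were higher in CMP, and of the 8 erythroid genes 7.

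Within GMP, neutrophil-like cells were compared with monocyte-like cells, the branches toward which this progenitor is known to mature. Each cell's UMIs were divided at random, so that classes were named on one part and genes tested on the other. GMP replicates 1, 2 and 3 held 1262, 1420 and 1387 neutrophil-like cells and 1983, 2402 and 2415 monocyte-like cells. The neutrophil-like cells formed a cluster of 2628 cells, named from Gstm1, Gfi1 and Cebpe and led by Vcam1, and a cluster of 1441 cells led by S100a9. In the clustering of all libraries 2, 0 and 3 GMP cells had this name, beside 69 LMPP cells led by Ngp and Camp, so here it covers other cells. Neutrophil-like cells carried more RNA of the tetraspanin gene Cd63, at 611 ± 78.7 CPM (SD, n = 3) against 139 ± 10.3 in monocyte-like cells (2.12 ± 0.03, log2 ± SE). Nkg7, a granule membrane protein gene, averaged 1319.9 ± 98.2 against 391 ± 12.5 CPM (1.75 ± 0.03). Monocyte-like cells carried more Emb, 302 ± 20.8 against 77.7 ± 10.8 CPM (-1.95 ± 0.04), and more Ighm, the immunoglobulin mu constant region (-2.65 ± 0.06). The edgeR quasi-likelihood test with library as a block passed 5066 of 11886 genes, with 2555 higher and 2511 lower in neutrophil-like cells, of which 309 and 440 were over 2-fold apart. Without the block for library, 1779 genes passed (869 higher, 910 lower), and the DESeq2 Wald test passed 2662.

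Other genes higher in neutrophil-like cells were B4galt6 (1.74 ± 0.06, adjusted p = 6.05e-20) and Vat1 (1.66 ± 0.05, adjusted p = 6.08e-22). Other genes higher in monocyte-like cells were Milr1 (-2.22 ± 0.07, adjusted p = 1.66e-22), Rassf4 (-2.11 ± 0.06) and the transcription factor gene Klf2 (-1.71 ± 0.07). Each lay on the same side in all 3 libraries. S100a9 (4.73 ± 0.04), Wfdc21 (3.96 ± 0.07), S100a8 (3.39 ± 0.05), Pglyrp1 (2.73 ± 0.04), Rflnb (1.85 ± 0.06) and Ltb4r1 (1.61 ± 0.04) were higher in neutrophil-like cells. Cxcl2 (-3.01 ± 0.09), Prdx4 (-2.95 ± 0.09), Ms4a6c (-2.68 ± 0.03), Ccl3 (-1.82 ± 0.07) and Cybb (-1.64 ± 0.06) were higher in monocyte-like cells. These 11 genes were among the 10 leading genes of a cluster of their class, so they describe the classes rather than a difference found between them. The other named genes are not free of this, since the classes were formed by clustering the same cells on expression. With undivided counts, B4galt6 was among the 10 leading genes of a neutrophil-like cluster, and Milr1 and Rassf4 of a monocyte-like one. Their p-values therefore do not test whether the classes are distinct.

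No list test was run between these GMP classes, and lists are given as counts. Of 34 S phase genes, 24 were lower in neutrophil-like cells and 1 higher, and of 52 G2M phase genes 37 were lower (38 adjusted over the list alone) and 5 higher, with Kif23, a mitotic kinesin gene, at -0.91 ± 0.08. The phase counts may depend on which clusters earned names, since 1 monocyte-like cluster was led by Klf4 and the histone gene Hist1h1b, while clusters led by Ube2c, Cdkn3 or histone genes stayed unnamed. In counts that were not divided, Rfc2, E2f8 and Rrm1 of the S phase list and Hmgb2 and Gtse1 of the G2M phase list turned to the other direction. Of 15 immediate early and heat shock genes, 14 were lower in neutrophil-like cells, with Atf3 at -1.92 ± 0.10 and Fos at -1.43 ± 0.04. Of 80 ribosomal protein genes, 77 were higher in neutrophil-like cells, with a median of 0.17 over the list, and none was lower, and of 15 ribosome biogenesis genes 4 were higher and 4 lower. Azurophil granule genes were higher in 5 of 6 cases, with Prss57 at 1.44 ± 0.03 and the granule proteoglycan gene Srgn at 1.37 ± 0.02. Of 3 specific and gelatinase granule genes, 2 were higher and Mmp8 lower (-3.67 ± 0.42). The 2 higher ones were S100a8 and S100a9, which lead a neutrophil-like cluster and so describe the class. Of 28 lineage transcription factors, 13 were higher and 7 lower (8 adjusted over the list alone), with Myb at 0.83 ± 0.03. Among other genes of fixed lists, the iron exporter gene Slc40a1 (3.73 ± 0.20) was higher in neutrophil-like cells, and H2-DMb1 (-2.83 ± 0.12) and the interleukin 6 receptor gene Il6ra (-1.53 ± 0.08) in monocyte-like cells.

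**Figure D5:**
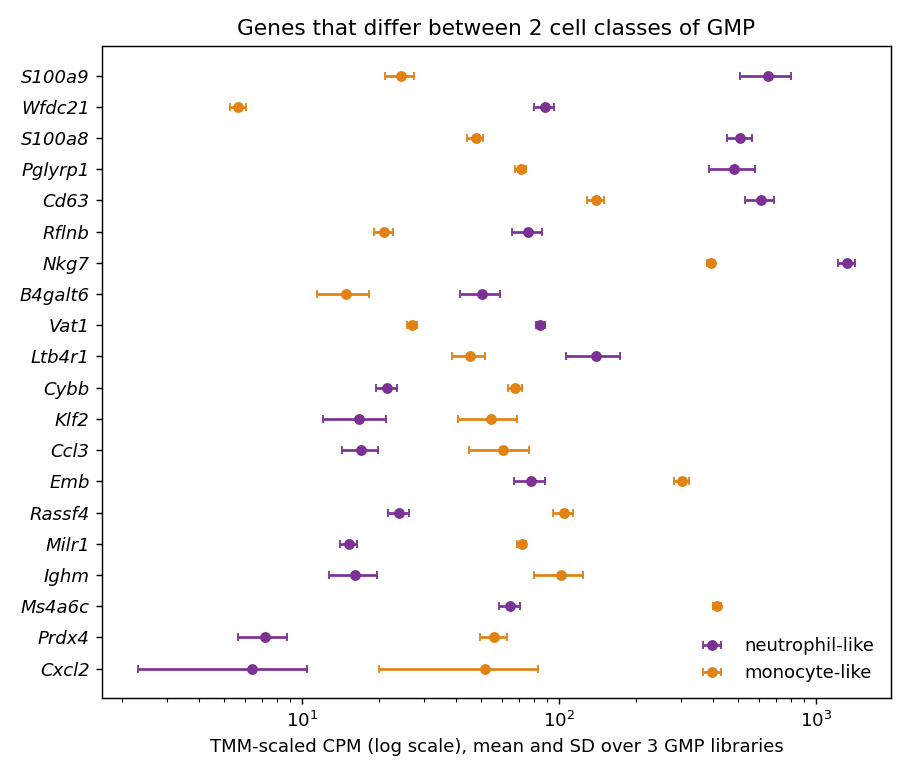
TMM-scaled CPM (log axis) in neutrophil-like and monocyte-like cells of GMP for the genes named by the fixed rule, with points for means and bars for the SD over 3 libraries. Nkg7 averages 1319.9 CPM in neutrophil-like cells and 391 in monocyte-like cells.

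To ask what still differs between cells given the same class name, GMP was compared with CMP within monocyte-like cells, of which CMP held 179 and the GMP libraries 3111, 3184 and 2971. Monocyte-like cells of GMP had more RNA of S100a8, at 55.4 ± 8.22 CPM (SD, n = 3) against 1.85 from 7 CMP UMIs (4.90 ± 0.38, log2 ± SE), Elane at 10800.4 ± 1411 against 2525 (2.10 ± 0.26) and Cebpe at 71.9 ± 2.98 against 19 (1.92 ± 0.18). Monocyte-like cells of CMP had more Sox4, a progenitor transcription factor, at 384 CPM against 163 ± 14.3 (-1.24 ± 0.15), and more Ctla2a, at 147 against 17.2 ± 4.60 CPM. Pglyrp1, a bactericidal peptidoglycan receptor gene, was higher in GMP by 3.95 ± 0.39, Nkg7 by 2.70 ± 0.19, Ms4a3 by 2.49 ± 0.21, Dstn by 2.26 ± 0.20, Prss57 by 2.01 ± 0.16, Gstm1 by 1.70 ± 0.17 and Ly6c1 by 1.70 ± 0.19. Rgs1 was lower in GMP by -1.99 ± 0.33, Marcksl1 by -1.75 ± 0.21, the chemokine gene Ccl3 by -1.41 ± 0.24, Btg2 by -1.33 ± 0.19, Lat2 by -1.29 ± 0.17, the kinase gene Pim1 by -1.24 ± 0.19, Junb by -1.23 ± 0.16 and BC064078 by -1.18 ± 0.20. The edgeR quasi-likelihood test passed 139 of 15570 genes, 77 higher and 62 lower in GMP. The count moved to 1912 without GMP replicate 1, 373 without replicate 2, 495 without replicate 3, 400 with the DESeq2 Wald test and 783 without the low-count filter. All 3 GMP libraries lay on the same side of CMP for each gene named here. Free RNA was not subtracted, so part of the excess in GMP may come from other cells, as weighed further below.

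Pairs of lineage regulators were tested for detection in the same cells, after each cell was thinned to 2000 UMIs. The odds ratios were taken over all cells of a library with the classes pooled, and not within a class. Classes that differ in both regulators can give such values by their mix alone, so these do not show how regulators relate within a class. In GMP, Irf8 and Cebpe were found together less often than independence gives, with a mean log2 odds ratio of -0.81 ± 0.08 (SD, n = 3), and so were Irf8 and Gfi1, a neutrophil regulator (-0.76 ± 0.05). Irf8 was detected in 49.8%, 48.4% and 56.3% of monocyte-like cells of GMP replicates 1, 2 and 3, and in 9.23%, 9.98% and 11.7% of granulo-monocytic-like cells. Irf8 was among the markers that named the monocyte-like clusters, and Gata1 among those that named the erythroid-like clusters. The detection of each in its own class follows from the naming and is no separate evidence. Erythroid-like cells, taken as background, had Irf8 in 11.5% and 5.94% of cells in replicates 1 and 2, with median depths of 8935.5 and 9289 UMIs against 11989 and 14088 in monocyte-like cells. Cebpe was detected in 31.1%, 33.5% and 38.5% of granulo-monocytic-like GMP cells and in 3.85% and 6.93% of erythroid-like ones (replicates 1 and 2), and Gfi1 in 3.82%, 4.48% and 5.04% and in 0% and 0%. These erythroid-like cells numbered only 52 and 101, so 0% leaves room for a background of a few percent. Gata1 and Gata2, regulators of erythroid, megakaryocyte and mast cells, were found together more often than independence gives, with 2.58 ± 0.31 in GMP and 1.29 (95% interval 0.98 to 1.61) in CMP. The GMP value rests on only 14, 18 and 6 cells with both genes in replicates 1, 2 and 3. In CMP, Gata1 and Spi1, the myeloid and lymphoid regulator PU.1, were found together less often (-1.24, -1.67 to -0.82), with Gata1 in 18.0% of erythroid-like and 0% of monocyte-like CMP cells and Spi1 in 11.7% and 44.7%. In GMP monocyte-like cells, the background for Gata1, it was detected in 0.161%, 0.220% and 0.0675% of cells. No background class was set for Spi1 or Gata2. In CMP, Dntt and Mpo were found together more often (1.10, 0.88 to 1.32). In LMPP, Dntt and Mpo had a log2 odds ratio of 0.57 (0.37 to 0.77), or 0.87 at 1000 UMIs, with Mpo in 14.6% and Dntt in 4.17% of erythroid-like LMPP cells, taken as background. Mpo was detected in 41.1% of erythroid-like CMP cells, taken as background, and 79.1% of B cell-like ones, and Dntt in 3.72% and 88.6%. In GMP the values of Gata2 with Cebpa (0.21 ± 0.18) and Gata1 with Spi1 (-0.51 ± 0.61) were close to or below their spread.

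S and G2M phase genes were summed as a share of all UMIs. The S phase share was 0.308% ± 0.0109 (SD, n = 3) in GMP, 0.319% in CMP and 0.321% in LMPP, and as a mean over cells 0.306%, 0.273% and 0.271%, which turns the order. The G2M phase share was 0.548% ± 0.0364 in GMP, 0.517% in CMP and 0.670% in LMPP, and as a mean over cells 0.509%, 0.411% and 0.515%. Within GMP, the S phase share was 0.326% ± 0.0167 in monocyte-like cells and 0.276% ± 0.00933 in granulo-monocytic-like cells, with the same order in all 3 libraries. Over TMM-scaled genes, 21 of 34 S phase genes were higher in GMP than in LMPP (camera adjusted p = 8.27e-06, adjusted p = 0.338 with an estimated correlation), but their median of 0.53 turned to -0.09 with scaling by total UMIs, where 3 were higher and 7 lower. Against CMP, 8 S phase genes were higher and 1 lower (camera adjusted p = 0.000144, adjusted p = 0.319 with an estimated correlation), and the median of 0.23 turned to -0.07. Of 52 G2M phase genes, 15 were higher and 1 lower against CMP (camera adjusted p = 5.47e-06, adjusted p = 0.399 with an estimated correlation). Against LMPP, 18 were higher and 7 lower (camera adjusted p = 0.0430, or 0.140 without GMP replicate 2 and 0.0670 without replicate 3, and adjusted p = 0.652 with an estimated correlation). With scaling by total UMIs, 5 G2M phase genes were higher and 3 lower against CMP, and 3 higher and 29 lower against LMPP, whose median of 0.16 turned to -0.46. Free RNA enters such sums in every cell, and how far it differs between libraries was not measured.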

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

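Of the values that answer a comparison, 195 stayed within a set tolerance of the main value under the alternatives and 64 moved beyond it. Values within the tolerance were not equal to the main value in all cases, and a gene count within it could still differ by many genes. Named genes kept their call in 3614 cases, 113 became weaker, 31 stronger and 12 reversed. Gene lists kept theirs in 297 cases, 75 became weaker, 12 stronger and 3 reversed. The count for GMP against CMP stayed between 5409 and 6910 under the alternatives other than leaving out a library or scaling by total UMIs, and that for GMP against LMPP between 8964 and 11885. The Wald test gave 2700 higher and 2709 lower against CMP, and 4714 and 4250 against LMPP, where the main test had more lower than higher. Scaling by total UMIs, chosen after seeing the data, gave 1435 higher and 5941 lower against CMP and 2150 and 10210 against LMPP, and reversed Tubb4b (-0.17) and Hmgb2 (-0.16) against LMPP; its construction lowers every GMP value. Leaving out each GMP library in turn gave 2063 to 4504 genes higher than in CMP. Without the neutrophil-like cluster, also chosen after seeing the data, S100a8 (0.94) and S100a9 (0.48, not past 0.05) reversed against LMPP, as did the specific granule list (adjusted p = 0.727), because that cluster holds most of their UMIs.

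With an estimated correlation 0 lists passed against CMP and 0 against LMPP. Lists with an estimated correlation below the preset 0.01 lost their call too. Such were azurophil granule (-0.00918), S phase (-0.0137) and lymphoid-primed (-0.0386), each at a camera adjusted p of 0.319 against CMP. For these lists the values argue against correlation between members as the cause. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom of the fit, where few lists can pass. The erythroid list, with an estimated correlation of 0.549, had the same adjusted p of 0.319 against CMP. The loss of all calls therefore does not decide which lists hold. The fry test called the cytokine receptor list lower in GMP (adjusted p = 0.00920 against CMP and 0.0126 against LMPP). Camera had pointed up without a call (adjusted p = 0.854 and 0.376), so the list counts as reversed though no call was lost. Of the other lists, 7 calls became weaker with fry and 8 stronger. Among the weaker ones were G2M phase (fry adjusted p = 0.0857 against CMP and 0.164 against LMPP) and ribosomal proteins against CMP (0.0721). The cause was not tested. CMP against LMPP gave 8 and 27 genes with CPM of total UMIs and 149 and 46 at 2-fold, the latter by construction.

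Within GMP, 1779 genes passed without the library block (869 higher, 910 lower), which leaves library differences in the error, and 2662 with the Wald test (1471 and 1191), the cause of which was not tested. Undivided counts reversed Rfc2 (0.0418), E2f8 (0.11), Rrm1 (0.00374), Hsp90b1 (-0.0879), Hmgb2 (0.32), Cd79b (-0.23) and Gtse1 (0.0803), where classes and genes come from the same counts, and having no filter reversed Aldoa (-0.54). Within monocyte-like cells, the Wald test gave 400 genes (204 and 196), no filter 783 (439 and 344), and leaving out each GMP library 373 to 1912 (184 to 944 higher, 189 to 968 lower). The causes were not tested.

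Clustering choices moved shares. At resolution 2 the monocyte-like share of GMP was 25.1% ± 7.48 (SD, n = 3), from 18.2% to 33.0%, and the granulo-monocytic-like share 23.7% ± 5.70. The erythroid-like share of CMP was 19.2% there, with a megakaryocyte-like share of 8.46%. Monocyte-like cells made up 3.15% of CMP at resolution 0.5, 3.15% without cell cycle genes and 3.01% with doublet calls kept. Neutrophil-like cells made up 1.77% of LMPP at resolution 2, 0.626% at 0.5 and 0.647% with doublet calls kept. At resolution 0.5 the granulo-monocytic-like share of GMP was 49.1%, the stem and multipotent-like share of LMPP 68.6%, and the B cell-like share 0 in CMP and 0 in LMPP. The erythroid-like share of CMP was 20.1% without cell cycle genes and 20.8% with doublet calls kept, which gave 32.2% granulo-monocytic-like cells in GMP; both settings named a megakaryocyte-like cluster in CMP (7.89% and 7.89%). As means over cells, S phase shares were 0.271% in LMPP and 0.273% in CMP, and G2M phase shares 0.515%, 0.411% and 0.509% in LMPP, CMP and GMP. Log2 odds ratios at 1000 and 4000 UMIs were -0.87 and -0.68 for Irf8 with Gfi1 and -0.95 and -1.01 for Irf8 with Cebpe in GMP, and 0.78 and 1.37 for Dntt with Mpo in CMP. At 1000 UMIs Gata2 with Cebpa gave 0.56 in GMP and Dntt with Mpo 0.87 in LMPP. Gata1 with Gata2 in GMP gave 3.75 at 4000 UMIs and 3.14 with doublet calls kept, and 0.92 in CMP with doublet calls kept. The causes of these shifts were not tested. Depth limits detection of regulators: 63 LMPP, 49 CMP, and 262, 111 and 78 GMP cells held too few UMIs for the main thinning.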

Other observations

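The gene and list tests of this paragraph were planned; of the tests of explanations below, the top 1% test of Igkc and both tests within monocyte-like cells were set before their result was seen, and the other tests were chosen only after it was seen. Of 7 MHC class II genes, 3 were lower in GMP than in CMP and 1 higher, with H2-Ab1 at -1.62 ± 0.15 (log2 ± SE) and H2-DMb1 at 1.73 ± 0.21. Against LMPP, 5 were lower and 2 higher, with H2-Ab1 at -2.27 ± 0.15 and the class II regulator gene Ciita at -3.11 ± 0.37. The camera adjusted p was 0.393 against CMP and 0.0825 against LMPP (adjusted p = 0.553 and 0.376 with an estimated correlation). Against LMPP the camera value fell to 0.00349 without GMP replicate 2 and 0.00328 without replicate 3. Dendritic cell-like cells, led by Cd74 and H2-Aa, numbered 34 in LMPP, 8 in CMP, and 12, 11 and 10 in GMP replicates 1, 2 and 3. Il7r, the interleukin 7 receptor gene, was lower in GMP than in CMP (-6.74 ± 0.22) and LMPP (-6.53 ± 0.22), and Epor, the erythropoietin receptor gene, was lower than in CMP (-5.25 ± 0.29). Ebf1, a B cell transcription factor gene, was lower than in CMP (-3.77 ± 0.26) and LMPP (-4.08 ± 0.26). An unnamed cluster of 461 cells led by Cxcl10 and Tnf had a median of 2837 UMIs per cell, and 272 of its cells came from GMP replicate 1.

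Camp, Ngp, Ltf, S100a8 and S100a9 were above their CMP level in LMPP, although the lineage antibodies, which include Gr-1 and CD11b, should remove mature neutrophils. The neutrophil-like cluster of 69 LMPP cells held 86.2% of their LMPP UMIs. The remaining 13.8% lay outside it. They still stood 62.5-fold over CMP once the 2 CMP cells of the cluster were left out as well, which lowered CMP from 35.6 to 4.76 CPM. The shares therefore do not decide whether a few neutrophil-lineage cells or free RNA set LMPP over CMP. In the stem and multipotent-like, B cell-like and erythroid-like cells of LMPP, the 5 genes came to 2.27, 2.70 and 4.05 UMIs per cell, a 1.78-fold range. The other LMPP cells outside the cluster, such as granulo-monocytic-like ones, were left out of that range. It therefore does not decide whether the remainder is free RNA. Whether neutrophil-lineage cells belong to LMPP biology or escaped the sort could not be tested with 1 library.

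Igkc in LMPP came mostly from 1 cell, which held 12386 of 13626 UMIs. The 1% of LMPP cells with the most Igkc held 92.2% of its UMIs, which met the rule set in advance for plasma cells or doublets with them. That cell had 23537 UMIs in all and 856 of the 935 Jchain UMIs of LMPP. It had 0 UMIs of Mzb1, which plasma cells express. Mzb1 was not part of the rule set in advance, and because of it a plasma cell or a doublet with one was left open. Free RNA spreads over droplets, so it does not account for the 90.9% of Igkc UMIs in that cell. With that cell left out, Igkc CPM varied 1.81-fold between clusters but UMIs per cell 5.48-fold, so whether the remainder is free RNA stays open. No explanation beyond plasma cells, doublets with them and free RNA was tested.

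Within monocyte-like cells, Elane and Ms4a3 were higher in GMP than in CMP. Free RNA from other GMP cells may add to this: over the named genes, UMIs per cell in the GMP class lowest in the gene came to a median of 0.331 of the excess (0.199 for Elane, 0.503 for Gstm1 and 0.595 for Cebpe), which leaves the question open. Within the cluster with most CMP cells, which held 97 of 179, the log2 difference was a median of 0.920 of that over the class. Another mix of the monocyte-like clusters therefore does not explain most of the difference in the named genes. A different mix of cells inside that cluster was not tested. For neutrophil-like against monocyte-like cells within GMP, 1 of the 10 splits of the 6 class sums, the real one, had as many genes (5066 against at most 0 in the others), and 10 splits cannot give a share under 0.05.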
